A study of Mus musculus with 12 samples.

How the data were processed

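Yolk sacs of wild type and Hypb knockout mouse embryos were profiled at embryonic day 9.0 (E9.0) and E10.5 on Affymetrix whole-genome mouse expression arrays. These are single-colour arrays on which each transcript is read by 1 or more probe sets. Per the labels, each sample was a pool of 4 yolk sacs of 1 genotype, the strain was given as 129Sv/C57BL/6, and biotinylated cRNA was made from 5 micrograms of total RNA. The design text gives 3 biological repeats per genotype and stage, so each of the 4 groups held 3 arrays and there were 12 arrays in all. Groups and replicate numbers were taken from the sample titles.

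The values used here are log2 expression values that the authors made with RMA, per the submitters' processing notes. RMA corrects the background, normalises the arrays to a common distribution and summarises the probes of each probe set. Its version was not given in the sources used here. The deposited table held 45101 probe sets with values from 2.03 to 14.49, given to 2 decimals. The array medians lay between 5.27 and 5.34, and Spearman correlations between pairs of arrays lay between 0.973 and 0.994. RMA gives no detection call and no depth, so the number of arrays limits the precision here, and the log2 changes of dim probe sets are compressed towards 0. Normalising all arrays to 1 distribution also removes any change shared by all transcripts. The scanner files were not used here.

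The 64 control probe sets were left out of all tests. Probe sets were named through the platform annotation: 34945 carried 1 gene symbol, 932 carried several and 9160 had no entry, and only those with 1 symbol entered the gene tests. For each gene the probe set with the highest mean over the 12 arrays was used, which gave 18193 genes, of which 9010 had more than 1 probe set. Of these genes 18032 were matched to the reference gene table by gene ID, and 0 symbols had to be renamed.

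A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation with 8 residual and 4.56 prior degrees of freedom. There were 5 comparisons: knockout minus wild type at each stage, the difference between those effects, and E10.5 minus E9.0 in each genotype. The tests were two-sided, and every adjusted p is a Benjamini-Hochberg value with a threshold of 0.05 over the genes of 1 comparison. Errors are standard errors (SE) of the fitted log2 change, or standard deviations (SD) over the 3 arrays of a group. Correlations across genes treat genes as points and not as independent replicates. For comparisons that share arrays, 200 simulations of unchanged groups gave the value that arises with no effect of knockout or stage. Their genes were drawn independently of each other.

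Before the data were examined, 22 gene lists holding 667 genes were fixed for yolk sac cell types, for other tissue that dissection can carry over, and for pathways. Of their members 604 were measured here. Each list was tested with limma's camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists, and with camera with an estimated correlation and with fry as alternatives. Counts of list members are given over all genes tested and adjusted over the list alone. Some lists share members.

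The genes named were chosen by a rule written before the data were examined. In each knockout comparison it takes the 12 largest rises and 12 largest falls among genes past the threshold whose 3 knockout arrays all lay on 1 side of the 3 wild type arrays. It also takes the 5 largest in each direction for the difference between stages, the 8 largest in each direction for each stage comparison, up to 4 members of each list by smallest p, and all called members where 5 or fewer passed. Setd2, Vegfa, Kdr, Tek, Pecam1, Notch1, Afp, Hba-x and Hbb-bh1 were always included. Symbols that are only clone or model identifiers were passed over, which left out 2 falls at E9.0. A gene named outside this rule is said to be so.

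Control probe sets were inspected for technical batches. On the E9.0 arrays the BioC hybridisation control exceeded BioB by 0.15 in replicate 3 of the knockout and 0.24 in replicate 3 of the wild type, against 1.70 to 1.86 on the other 4 arrays. On the E10.5 arrays the dap spike's 3' minus 5' difference was 1.65 and 1.63 in replicate 3 of knockout and wild type, against 0.87 to 1.18 on the others. Replicate 3 was therefore treated as a batch at each stage. This batch was inferred from the controls and is not named in the labels. It holds both genotypes, so counts are given with a batch block and within replicates 1 and 2. Replicate 3 alone is 1 array against 1, which gives a difference but no test.

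The fit was tested on simulated data of 18193 genes with 200 genes changed by known amounts. At E9.0, 68 of 68 genes with a log2 change of 2, 64 of 66 with a change of 1 and 18 of 66 with a change of 0.5 were recovered, with 5 false calls. At E10.5 the recovered numbers were 68 of 68, 62 of 66 and 18 of 66, with 2 false calls. In the list test at E10.5, 0 of 22 lists passed with no effect simulated and 1 passed, the interferon list, when it was moved by 0.5. The simulated genes varied independently, while the estimated correlation in the data was 0.539 for the primitive erythroid list. The simulation therefore cannot show how the list test behaves with correlated genes.

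The alternatives were all probe sets, the mean of a gene's probe sets, genes brighter than the median gene, a further quantile normalisation, median centring, an intensity trend with a robust prior, array weights, a replicate block, genes within 10 Mb of Setd2 left out, only the 6 arrays of a comparison, a 2-fold minimum, and each array left out in turn. Replicates 1 and 2 alone, the batch block and the combination of 6 arrays with a replicate block were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.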

Results

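Expression was measured in pools of yolk sacs, the extraembryonic membrane that feeds the early embryo and makes its first blood and vessels. Hypb, now named Setd2, encodes the enzyme that places trimethylation on lysine 36 of histone H3 along transcribed genes. The submitters chose E9.0 because the knockout looks close to normal then, and E10.5 because defects are visible shortly before death. Each of the 4 groups held 3 arrays, each from a pool of 4 yolk sacs, and 18193 genes were tested with a median SE of 0.126 on the log2 scale for a comparison of 2 groups. Values are deposited log2 RMA values, for which no depth exists, so the number of arrays sets the precision.

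Setd2 itself was lower on every knockout array than on every wild type array at both stages. At E9.0 its mean was 7.69 ± 0.26 (SD, n = 3) in the knockout and 8.98 ± 0.13 (SD, n = 3) in the wild type, a log2 change of -1.29 (SE 0.13; 2.45-fold lower; adjusted p = 0.00207). At E10.5 it was 7.88 ± 0.16 in the knockout and 8.71 ± 0.056 in the wild type, a log2 change of -0.83 (SE 0.13; 1.77-fold lower; adjusted p = 0.00294). Setd2 was read by 1 probe set, and the labels do not give the deleted part of the gene, so the remaining signal has no reading as residual protein. The changes were -1.29 and -0.95 within replicates 1 and 2.

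**Figure D1:**
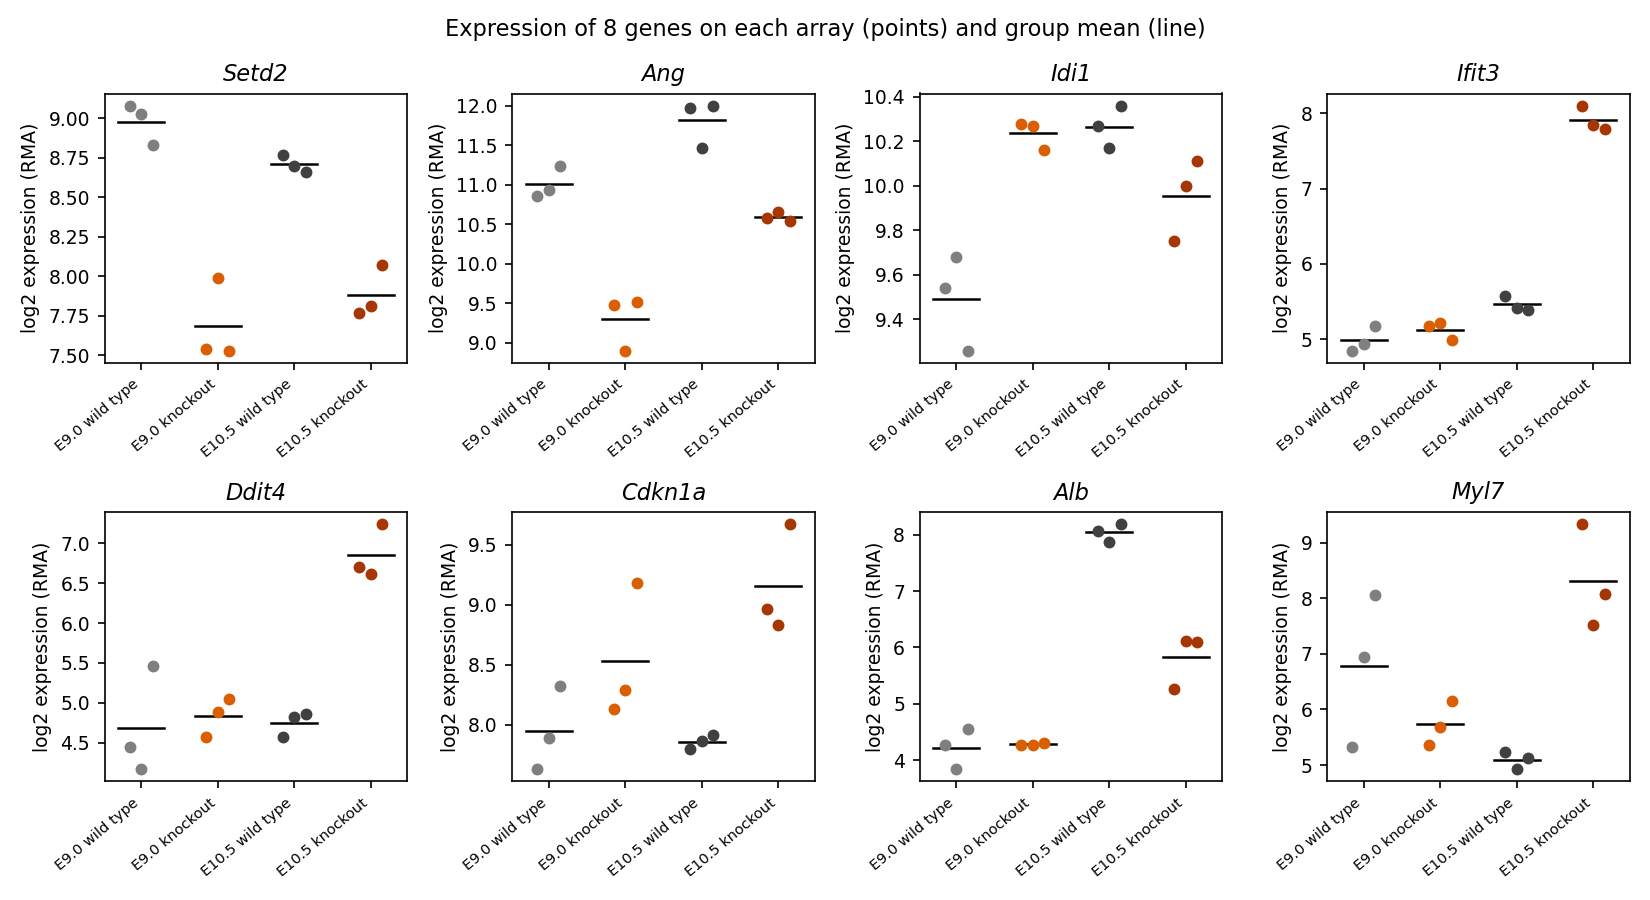
Log2 RMA expression of 8 genes on each array, with points for the 3 arrays of a group and a line for the group mean. Setd2 is lower on all knockout arrays at both stages, and the genotypes do not overlap for any of the 8 genes at E10.5.

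At E9.0 the largest rises in the knockout were in Cldn1, a tight junction protein, which rose by 1.77 (SE 0.36; adjusted p = 0.0372), Ociad2 (1.46, SE 0.20), Ctla2b (1.40, SE 0.26) and Ankrd1 (1.40, SE 0.27). Ddx4, the germ cell RNA helicase, rose by 1.35 (SE 0.15), Kng1, which encodes kininogen, by 1.31, and Fcer1g, the shared gamma chain of Fc receptors, by 1.29. The vesicle traffic gene Rab6b, the trefoil factor Tff3, and Snap91, Clrn3 and Kif5c also rose, by between 1.06 and 1.29. The largest falls were in Tmed6, at -2.28 (SE 0.49; adjusted p = 0.0453), the protocadherin Pcdh17, at -2.26 (SE 0.27), and Ang, which encodes the secreted ribonuclease angiogenin, at -1.71 (SE 0.18; adjusted p = 0.00207). Rnf17, a germ cell protein, fell by 1.69, Pnma5 by 1.65, Urah by 1.47, Tmem54 by 1.40, the endothelial connexin Gja4 by 1.36, the guidance ligand Slit2 by 1.35, Clcn4 by 1.32, Zik1 by 1.30 and the alcohol dehydrogenase Adh1 by 1.29. In all, 215 genes changed, 100 higher and 115 lower in the knockout, 45 of them by at least 2-fold, and 2149 had an unadjusted p under 0.05. In 3271 genes (18%) the 3 knockout arrays did not overlap the 3 wild type arrays, where chance gives 10%. Of the 24 genes with the largest changes, 10 kept their call without any 1 array: Ociad2, Ddx4, Fcer1g, Snap91, Kif5c, Pcdh17, Ang, Rnf17, Tmem54 and Zik1. All 24 kept their sign without any 1 array, which the rule of non-overlapping arrays fixed in advance. Another probe set of Cldn1 gave -0.09 and another of Snap91 gave -0.057, neither past the threshold, and Rab6b lies within 10 Mb of Setd2. The number of calls fell to 33 without knockout replicate 1, 49 without knockout replicate 3, 54, 44 and 136 without wild type replicates 1, 2 and 3, and 182 without knockout replicate 2. It was 476 with the batch block and 69 within replicates 1 and 2, of which 41 were among the 215. All 215 genes kept their sign there. This was fixed in advance, since the arrays of the genotypes did not overlap for the 100 higher and 115 lower genes.

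Among the fixed lists, genes of cholesterol synthesis were higher in the E9.0 knockout. Of 20 measured members 4 rose over all genes tested and 12 adjusted over the list alone, 0 fell, and the list median was 0.49 (camera adjusted p = 1.68e-13; adjusted p = 0.139 with an estimated correlation). The members that rose were Idi1 (0.74, SE 0.12), Insig1 (0.71), the squalene epoxidase gene Sqle (0.68) and the lanosterol synthase gene Lss (0.66). The median was 0.50 within replicates 1 and 2 and 0.55 in replicate 3. Of 27 measured p53 targets and apoptosis genes, 2 rose over all genes, Ccng1 (0.68) and Trp53inp1 (0.53), and 7 rose adjusted over the list alone. Their list median was 0.26 (camera adjusted p = 2.15e-06; adjusted p = 0.339 with an estimated correlation), and it was 0.26 within replicates 1 and 2 and 0.23 in replicate 3. The basement membrane and parietal endoderm list passed the test (median 0.25; adjusted p = 0.00435; adjusted p = 0.818 with an estimated correlation), with 0 of 19 members called over all genes or over the list alone. It did not hold within batches: its median was -0.24 within replicates 1 and 2 (adjusted p = 0.403) and 1.06 in replicate 3. No call of a member of these lists held without every 1 array; without knockout replicate 1, for example, Idi1 gave 0.72 (adjusted p = 0.0938), and without wild type replicate 2 Ccng1 gave 0.64 (adjusted p = 0.0610).

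The other 19 lists did not pass at E9.0, the interferon list among them (median -0.05; adjusted p = 0.804; 0 of 26 called). The endothelium list had 0 of 30 members called and a median of 0.068 (adjusted p = 0.416), and Kdr, the main receptor of vascular endothelial growth factor, had a change of 0.003 (SE 0.21; adjusted p = 0.998). Tek gave -0.18 (adjusted p = 0.763), Pecam1 0.37 (adjusted p = 0.622), Notch1 -0.11 (adjusted p = 0.862) and Vegfa 0.20 (adjusted p = 0.556). In the arterial, venous and Notch list 1 of 25 members fell, Gja4, and 2 fell adjusted over the list alone. In the vascular remodelling list 1 of 47 fell, the integrin Itgb3 (-0.83), with 1 rising and 3 falling adjusted over the list alone. In the haematopoietic list the macrophage gene Cd68 rose by 0.65 and Tyrobp fell by 0.61, and 1 rose and 4 fell adjusted over the list alone. In the unfolded protein and amino acid stress list Atf3 rose by 0.53, with 1 rising and 1 falling adjusted over the list alone. No call of these members held without every 1 array. All kept their sign, as genes with non-overlapping arrays must. The highest adjusted p was 0.16 for Gja4 (-1.15) and 0.204 for Tyrobp (-0.53), each without knockout replicate 1, and 0.0584 for Cd68 (0.63) without knockout replicate 3. It was 0.166 for Itgb3 (-0.73) without wild type replicate 2 and 0.103 for Atf3 (0.47) without wild type replicate 1. The median, mean and test differed in sign for the visceral endoderm list (median -0.027, mean 0.014, tested lower) and the mesenchyme list (median -0.08, mean -0.012, tested higher). The visceral endoderm marker Afp changed by 0.057 (adjusted p = 0.901), and the embryonic globins Hba-x and Hbb-bh1 by 0.063 (adjusted p = 0.884) and 0.053 (adjusted p = 0.910). These 3 transcripts lie near the top of the measured range, where differences are compressed.

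At E10.5 the largest rise in the knockout was in Ankrd1, a stress-responsive ankyrin repeat protein, by 3.22 (SE 0.27; 9.34-fold; adjusted p = 4.37e-05), and the atrial myosin light chain Myl7 rose by 3.21 (SE 0.56; adjusted p = 0.00477). Interferon-inducible genes rose from low levels: Oasl2 by 2.67 (SE 0.25), Ifit3 by 2.45 (SE 0.12; adjusted p = 7.70e-07), Ifit1 by 2.43, Ifi202b by 2.41, Usp18 by 2.37 and Gbp2 by 2.35, along with the chemokine Ccl12 by 2.47. Tpbg, the transcription factor Sox11 and the retinoic acid binding protein Crabp1 rose by 2.90, 2.47 and 2.30. The largest falls were in Tmed6, at -3.79 (SE 0.49; 13.8-fold; adjusted p = 0.000652), Lypd8 (-2.25), the albumin gene Alb (-2.22, SE 0.22; adjusted p = 0.000113), the transport partner Cltrn (-2.12), Adh1 (-2.09), Asb17 (-2.08), Tmem54 (-2.05), Clcn4 (-2), the platelet chemokine Ppbp (-1.98), Pnma5 (-1.96), Rnf17 (-1.95) and Zik1 (-1.93). In all, 1325 genes changed, 750 higher and 575 lower (639 and 624 with median centring of each array), of which 284 changed by at least 2-fold, 170 up and 114 down, and 3680 had an unadjusted p under 0.05. In 4151 genes (22.8%) the arrays of the genotypes did not overlap. Of the 24 largest changes only Tpbg and Sox11 lost their call in any fit without 1 array. Without knockout replicate 1 Tpbg gave 2.62 (adjusted p = 0.0857) and Sox11 2.21 (adjusted p = 0.0914). Tpbg was also lost without knockout replicate 3 (2.36) and wild type replicates 1 (2.71) and 2 (2.72), and Sox11 without wild type replicates 1 (2.15) and 2 (2.29). The number of calls was 707 without knockout replicate 1, 768, 693 and 860 without wild type replicates 1, 2 and 3, 2081 with the batch block and 1610 within replicates 1 and 2, of which 944 were among the 1325. All 1325 genes kept their sign within replicates 1 and 2. For 743 of the higher and 570 of the lower genes the arrays of the genotypes did not overlap, so this was fixed in advance.

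The interferon response list showed the clearest shift at E10.5. Of 26 measured members 16 rose over all genes and 17 adjusted over the list alone, 0 fell, and the median was 0.49 (camera adjusted p = 8.96e-16; adjusted p = 0.0327 with an estimated correlation). Besides the genes above, and named after their values were seen, these included Rsad2 (2.02), Ifit2 (1.49), the RNA sensor gene Ifih1 (1.45), Ifitm3 (1.11) and Irf7 (0.71). It was the 1 list of the 16 past the threshold that held with an estimated correlation. Its median was 0.51 within replicates 1 and 2 and 0.52 in replicate 3, and it was 0.23 over its 12 members brighter than the median gene (adjusted p = 0.00436). Markers of white blood cells moved beside it in both directions: Cx3cr1 (0.65) rose, as did Csf1r (0.79) and Tyrobp (0.48), which were named after their values were seen, and the Fc receptor gene Fcgr3 fell by 1.82.

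Stress response lists were higher too. Of 33 hypoxia response genes 10 rose, 12 adjusted over the list alone, with a median of 0.28 (adjusted p = 4.52e-08; adjusted p = 0.198 with an estimated correlation). They included Ddit4 (2.10), an inhibitor of mTOR signalling, the prolyl hydroxylases Egln3 (1.38) and P4ha1 (0.91), the histone demethylase Kdm3a (0.65) and Vegfa (0.44, SE 0.11; adjusted p = 0.0343). Vegfa lost its call without knockout replicates 1 (0.48, adjusted p = 0.0682) or 3 (0.32), or without wild type replicates 1 (0.47), 2 (0.43) or 3 (0.44), and within replicates 1 and 2 (adjusted p = 0.0858). Of 27 p53 targets and apoptosis genes 10 rose, and 15 rose and 1 fell adjusted over the list alone, with a median of 0.43 (adjusted p = 7.72e-08; adjusted p = 0.198 with an estimated correlation). Among them were the death receptor Eda2r (1.59), the cell cycle inhibitor Cdkn1a (1.30), the kinase Plk2 (1.19) and Ccng1 (0.99). The hypoxia median was 0.31 within replicates 1 and 2 and 0.58 in replicate 3, and the p53 median 0.33 and 0.54. In the unfolded protein and amino acid stress list Chac1 (1.12) and Atf3 (0.57) rose, 5 of 30 rose adjusted over the list alone, and the list did not pass (adjusted p = 0.332); its median was -0.008 and its mean 0.11.

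Vessel and mesenchyme genes were higher in the E10.5 knockout. Of 30 endothelial genes 6 rose, 10 adjusted over the list alone, and the median was 0.36 (adjusted p = 1.47e-06; adjusted p = 0.279 with an estimated correlation). They included Adgrf5 (1.15), the transcription factor Fli1 (1.04), the adhesion molecules Pecam1 (0.86, SE 0.24; adjusted p = 0.0453) and Icam2 (0.56) and the receptor Lyve1 (0.47), while Kdr gave 0.33 (adjusted p = 0.442) and Tek 0.15 (adjusted p = 0.697). Pecam1 lost its call without knockout replicates 1 (0.88, adjusted p = 0.116) or 3 (0.69), or without wild type replicates 1 (0.92), 2 (0.68) or 3 (0.99). Of 29 mesothelium, mesenchyme and smooth muscle genes 7 rose, 8 adjusted over the list alone, with a median of 0.29 (adjusted p = 2.85e-05; adjusted p = 0.278 with an estimated correlation), among them Tpm1 (0.82), Msx2 (0.78), the smooth muscle actin Acta2 (0.76) and Vim (0.76). Its median was 0.13 within replicates 1 and 2 and 0.49 in replicate 3, against 0.30 and 0.43 for the endothelial list. Of 47 vascular remodelling genes 6 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone (median 0.16; adjusted p = 0.000408; adjusted p = 0.279 with an estimated correlation). Ccn2 (2.11), Ccn1 (1.48), both matricellular proteins, and the vasodilator peptide gene Adm (1.39) rose, and Calcrl, part of the adrenomedullin receptor, fell by 1.06. The vascular remodelling median was 0.095 within replicates 1 and 2 and 0.38 in replicate 3. The Notch list did not pass (adjusted p = 0.5): Gja4 (-1.05) and Rbpj (-0.52) fell, also adjusted over the list alone, another Rbpj probe set gave 0.04, and Notch1 gave 0.25 (adjusted p = 0.359).

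Basement membrane and parietal endoderm genes were higher at E10.5, with 2 of 19 rising, Krt19 (1.11) and P4ha1, 3 adjusted over the list alone, and a median of 0.42 (adjusted p = 0.000292; adjusted p = 0.316 with an estimated correlation; 0.42 within replicates 1 and 2 and 0.45 in replicate 3). Of 29 imprinted genes 5 rose, Cdkn1c (0.85), Ndn (0.72), Igf2r (0.66), Grb10 (0.61) and Zim1 (0.61), and 6 adjusted over the list alone. Their median was 0.26 (adjusted p = 0.000408; adjusted p = 0.237 with an estimated correlation), 0.12 within replicates 1 and 2 and 0.27 in replicate 3, and another Ndn probe set gave -0.15. In the haematopoietic list 5 of 27 rose and 2 fell, and 9 rose and 3 fell adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0374; adjusted p = 0.279 with an estimated correlation; adjusted p = 0.0582 after a further quantile normalisation). The granule enzyme gene Mpo (1.56) rose, Ppbp and Fcgr3 fell, and the median was 0.19 within replicates 1 and 2 and 0.21 in replicate 3. The embryo proper list had 2 of 28 members rising, also adjusted over the list alone, the heart muscle genes Myl7 and Tnnt2 (1.92), with a median of 0.065 (adjusted p = 0.0177; adjusted p = 0.278 with an estimated correlation). Its median was 0.073 within replicates 1 and 2, where its adjusted p was 0.0514, and 0.13 in replicate 3. The cell cycle list had 2 of 37 rising, also adjusted over the list alone, the D-type cyclins Ccnd1 (0.76) and Ccnd2 (0.89), with a median of 0.073 (adjusted p = 0.0487; adjusted p = 0.316 with an estimated correlation; adjusted p = 0.0513 with the batch block). Its median was 0.030 within replicates 1 and 2 and 0.080 in replicate 3.

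Lists of red blood cell and endoderm function were lower in the E10.5 knockout. Of 34 primitive erythroid genes 2 fell, the membrane protein genes Epb42 (-1.25) and Rhd (-0.78), also adjusted over the list alone, with a median of -0.36 (adjusted p = 2.17e-05; adjusted p = 0.335 with an estimated correlation). Epb42 lost its call without knockout replicate 1 (-0.81, adjusted p = 0.0728) or wild type replicates 1 (-1.27), 2 (-1.33) or 3 (-1.15). Rhd lost its call without knockout replicates 1 (-0.55, adjusted p = 0.130) or 3 (-0.74), or wild type replicates 1 (-0.81), 2 (-0.82) or 3 (-0.72). The globins Hba-x and Hbb-bh1 gave -0.13 (adjusted p = 0.518) and -0.20 (adjusted p = 0.242). Of 20 cholesterol synthesis genes 3 fell, Mvd (-0.61), Msmo1 (-0.55) and Tm7sf2 (-0.52), and 5 adjusted over the list alone, with a median of -0.28 (adjusted p = 0.000408; adjusted p = 0.279 with an estimated correlation), while another Msmo1 probe set gave 0.08. Of 35 visceral endoderm genes 3 fell, the apolipoprotein gene Apoc1 (-1.13), the brush border gene Vil1 (-0.59) and the uptake receptor Cubn (-0.36), and the transcription factor Foxa1 rose by 0.93. Adjusted over the list alone 8 fell and 2 rose, the median was -0.13 (adjusted p = 0.00209; adjusted p = 0.279 with an estimated correlation), and Afp gave 0.010 (adjusted p = 0.971). Of 33 nutrient uptake and lipid transport genes 3 fell, Cubn and the transporters Abca1 (-0.57) and Abcg2 (-0.43), and 5 fell and 1 rose adjusted over the list alone (median -0.10; adjusted p = 0.0374; adjusted p = 0.316 with an estimated correlation; adjusted p = 0.107 after a further quantile normalisation and 0.0513 with the batch block). Of 29 oxidative phosphorylation genes 0 were called over all genes or over the list alone, with a median of -0.12 (adjusted p = 0.00787; adjusted p = 0.279 with an estimated correlation). Within replicates 1 and 2 the erythroid, cholesterol, endoderm, uptake and oxidative phosphorylation medians were -0.39, -0.35, -0.16, -0.11 and -0.14. In replicate 3 they were -0.20, -0.17, -0.10, -0.01 and -0.09.

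The remaining lists did not pass at E10.5. In the H3K36 methylation list 1 of 30 members fell, the DNA methyltransferase Dnmt3a (-0.43), 0 adjusted over the list alone (adjusted p = 0.347), and its other probe sets gave -0.30, -0.18, 0.16 and 0.23, none past the threshold. The trophoblast and decidua list had 1 of 29 rising, Plac1 (1.05), also over the list alone (adjusted p = 0.380). The histone list had 9 of its 29 members measured, with 0 called over all genes and 3 rising adjusted over the list alone (adjusted p = 0.119). The sex-linked list, which follows the mix of male and female embryos in a pool, did not pass at either stage (adjusted p = 0.716 and 0.486). It joins Xist, a female marker, with male markers that move the opposite way, so this test cannot show a changed mix. Its Xist value ranged from 5.89 to 10.91 over the 12 arrays and overlapped between the genotypes at both stages. At E10.5 Xist was 7.52, 10.41 and 5.89 in the knockout and 9.61, 9.56 and 10.91 in the wild type. The male marker Kdm5d was 6.44, 4.35 and 6.87 in the knockout and 6.32, 5.87 and 5.93 in the wild type. The mix therefore differed between the knockout pools, and an equal mix in the genotypes was not shown. Of the 55 called members named by the rule for lists at E10.5, which leaves Vegfa and Pecam1 to the genes always named, 36 kept their call without any 1 array. All 55 kept their sign, which cannot turn where the arrays of the genotypes do not overlap. The 19 that lost their call were Abcg2, Cdkn1c, Cubn, Dnmt3a, Epb42, Fli1, Foxa1, Gja4, Grb10, Icam2, Igf2r, Lyve1, Msmo1, Mvd, Ndn, Plac1, Rhd, Tm7sf2 and Zim1. Vegfa and Pecam1 lost theirs too, and the E10.5 genes named after their values were seen are not in this count.

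**Figure D2:**
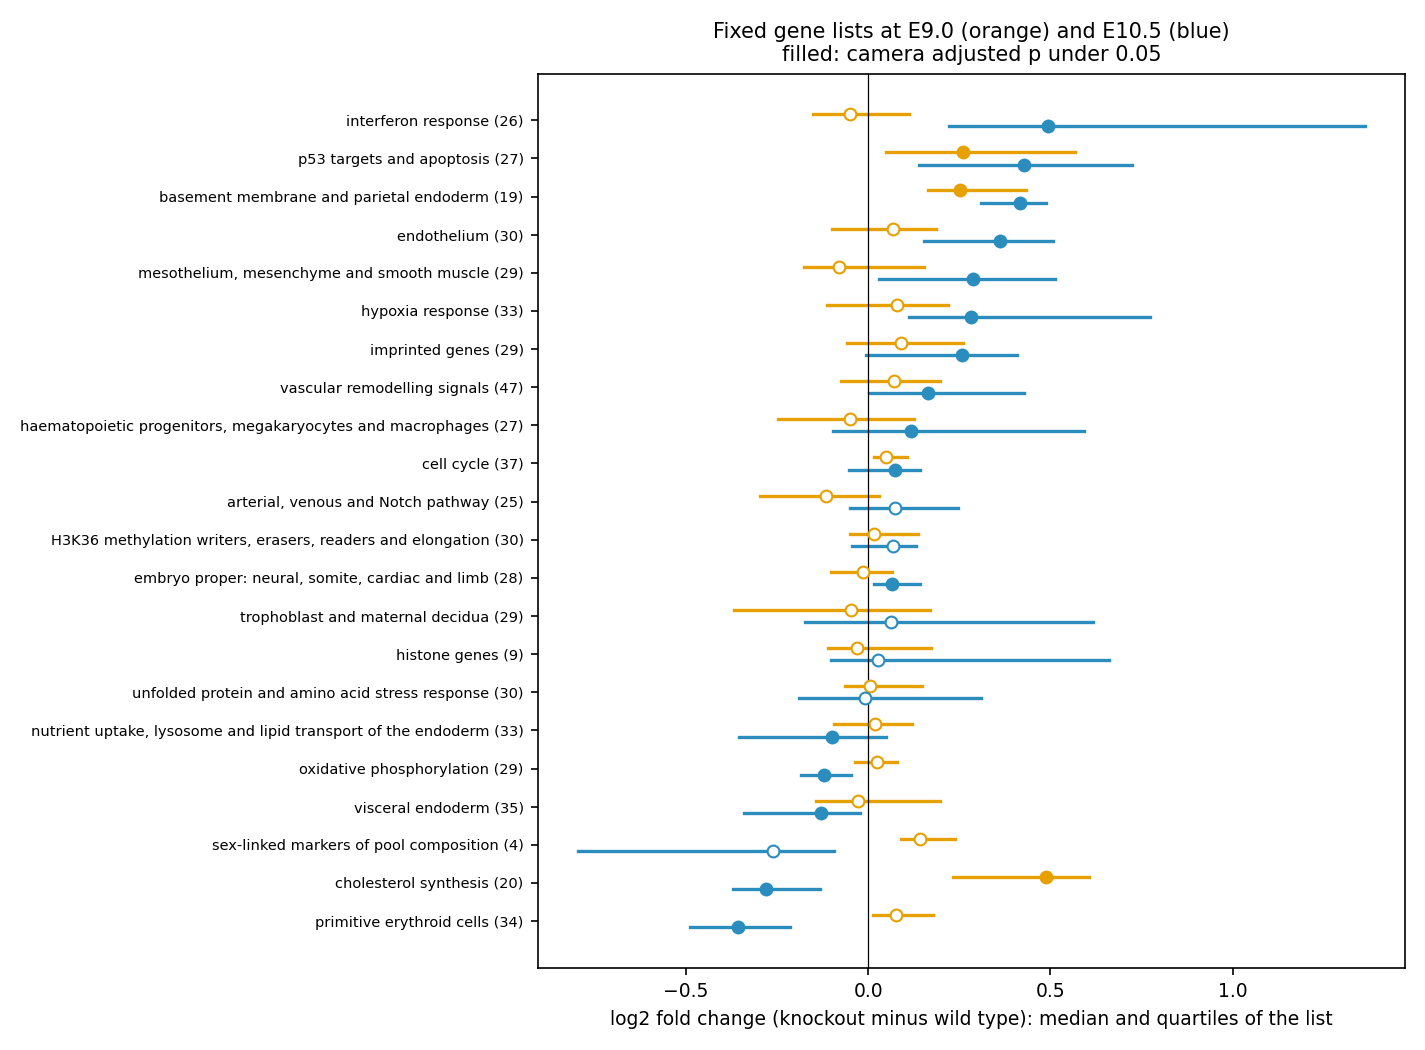
Median (point) and quartiles (line) of the log2 change, knockout minus wild type, for each of the 22 fixed lists, with the number of measured genes in parentheses. Orange is E9.0 and blue is E10.5, and filled points mark a camera adjusted p under 0.05 with the preset correlation; the cholesterol synthesis median is 0.49 at E9.0 and -0.28 at E10.5, and that of the interferon list -0.05 and 0.49.

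The knockout effects at both stages were set against each other to see how far the same genes moved. Of the genes changed at E9.0, 45 of the 100 higher ones were also higher at E10.5, where independent lists would share 4.12, and 74 of the 115 lower ones were also lower, where 3.63 would be shared. In all 120 genes changed at both stages, 119 of them in the same direction and Tyrobp in opposite directions (-0.61 and 0.48). Those that moved in the same direction included Ankrd1, Rab6b, Fcer1g, Pcdh17, Ang, Tmed6, Rnf17, Tmem54, Zik1 and Adh1. Of the 215 genes changed at E9.0, 197 (91.6%) had the same sign at E10.5. Across the 18193 genes the log2 changes correlated with a Pearson r of 0.475 and a Spearman rho of 0.386, and with r = 0.661 over the 1420 genes changed at either stage. The comparisons share no array, and simulations with no effect gave r between -0.037 and 0.038. The simulated genes varied independently, so this range leaves out variation that genes share. A jackknife, which leaves out each array in turn, gave r an SE of 0.092.

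**Figure D3:**
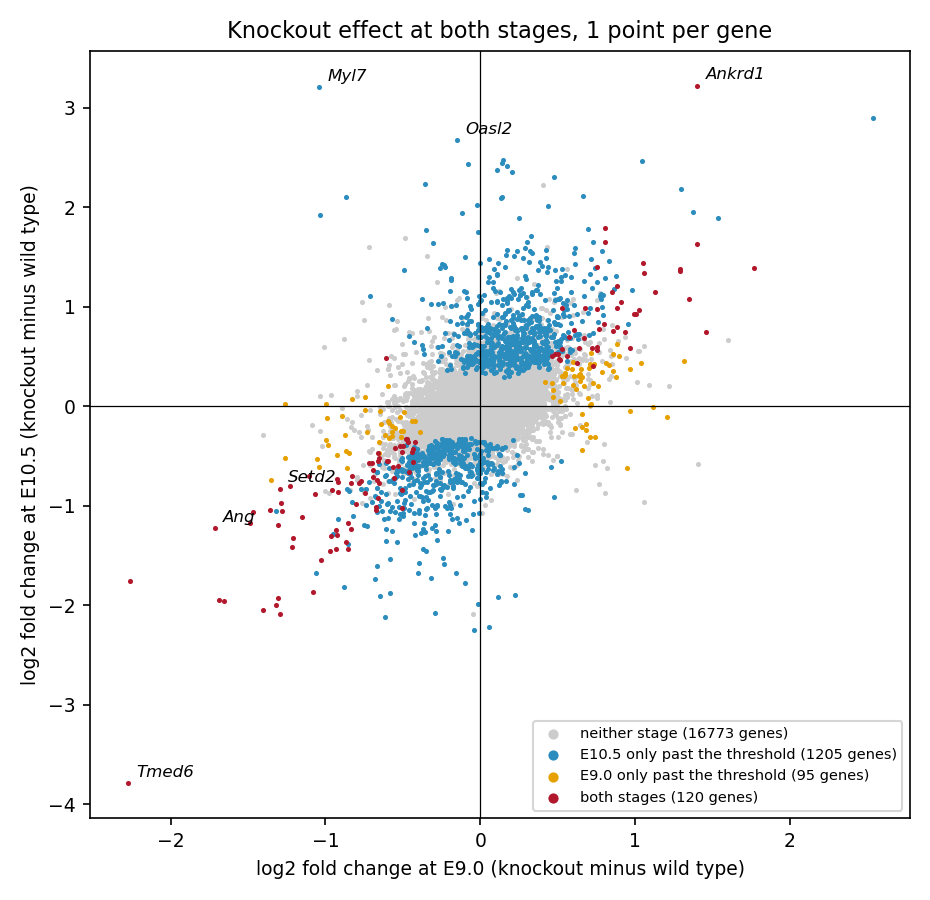
Log2 change, knockout minus wild type, at E9.0 (horizontal) and E10.5 (vertical), with 1 point per gene coloured by the stage at which it passed the threshold. Of the 120 genes changed at both stages 119 moved in the same direction, Tmed6 lowest and Ankrd1 highest, and Tyrobp moved in opposite directions, while Oasl2 and Myl7 passed the threshold at E10.5 only.

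The test of the difference between stages asked which genes responded to the knockout otherwise at E10.5 than at E9.0. The knockout effect was more positive at E10.5 for the heart troponin Tnnt2 (2.95, SE 0.51; -1.03 at E9.0, adjusted p = 0.235, and 1.92 at E10.5), Oasl2 (2.83, SE 0.35), Shisa3 (2.59, SE 0.35), Ifit1 (2.51, SE 0.25) and Ccl12 (2.33, SE 0.27). It was more negative for Alb (-2.27, SE 0.31), Lypd8 (-2.21), Prdm14 (-2.12, SE 0.16; adjusted p = 8.87e-05), Ppbp (-1.97) and Cltrn (-1.50). At E9.0 the means of Alb, Lypd8, Prdm14 and Ppbp lay between 3.53 and 4.35 in both genotypes, under the median gene at 6.52. A fall in the E9.0 knockout could therefore hardly be seen for these 4 genes. In all 34 genes differed, 19 more positive and 15 more negative at E10.5, and 1510 had an unadjusted p under 0.05. Of the 22 lists 16 passed, and the interferon list (median 0.53; adjusted p = 3.21e-21; adjusted p = 0.0127 with an estimated correlation; 6 of 26 called, 15 adjusted over the list alone) and the cholesterol list (median -0.66; adjusted p = 1.41e-19; adjusted p = 0.0254 with an estimated correlation; 4 of 20 called, 12 adjusted over the list alone) held with an estimated correlation. The cholesterol members were Lss, Msmo1, Idi1 and Insig1, at -1.09, -1.07, -1.06 and -1.02, and each of these 4 calls was lost in fits without 1 array. For Myl7, which rose at E10.5, the difference was 4.25 (SE 0.80; adjusted p = 0.0514). Of the 10 largest differences Oasl2, Shisa3, Ifit1, Ccl12, Alb and Prdm14 kept their call without any 1 array. The count was 91 with the batch block, 43 within replicates 1 and 2 and 0 over genes brighter than the median gene, where 680 of 9099 had an unadjusted p under 0.05. Without 1 array it was 17, 21 and 20 (E9.0 knockout replicates 1, 2 and 3), 20, 90 and 62 (E10.5 knockout replicates 1, 2 and 3), and 12 and 21 (E10.5 wild type replicates 2 and 3).

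Development from E9.0 to E10.5 was compared within each genotype. In the wild type the largest rises were in Ppbp (5.23, SE 0.22; 37.4-fold; adjusted p = 2.95e-08), Kng1 (4.38), the protease inhibitor Serpina1c (4.25), the coagulation factor gene F13b (3.85), Sgk2 (3.85), Alb (3.82), the glutathione transferase Gsta3 (3.81) and the monocarboxylate transporter Slc16a7 (3.71). The largest falls were in Ece1 (-2.64), Zfp934 (-2.31), Fgf13 (-2.21), Ddx6 (-2.10), Crim1 (-2.09), the DNA methyltransferase Dnmt3b (-2.07), Slco3a1 (-2.05) and Sema5a (-2.02). In all 4044 genes changed, 2432 up and 1612 down, with 4752 under the batch block and 3982 within replicates 1 and 2. Of 20 cholesterol synthesis genes 15 rose, 16 adjusted over the list alone, led by Cyp51 (1.58) and Msmo1 (1.47), with a median of 0.77 (adjusted p = 1.38e-09; adjusted p = 0.122 with an estimated correlation). In the haematopoietic list 16 of 27 rose and 1 fell, the same numbers adjusted over the list alone (median 0.67; adjusted p = 3.44e-06; adjusted p = 0.122 with an estimated correlation). Of 30 endothelial genes 13 fell and 1 rose, 15 and 1 adjusted over the list alone, Fli1 among the falls at -1.99 (median -0.45; adjusted p = 3.97e-05; adjusted p = 0.482 with an estimated correlation). Of the 22 lists 9 passed in the wild type, and 0 of them held with an estimated correlation. Ddx6 lost its call without wild type E10.5 replicate 3 (-1.82, adjusted p = 0.0504).

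In the knockout 4290 genes changed between stages, 2621 up and 1669 down, with 5144 under the batch block and 4907 within replicates 1 and 2. The largest rises were in Rtp4 (3.96, SE 0.26), the platelet factor Pf4 (3.65), Ifitm3 (3.54), Kng1 (3.53), the caveolin Cav1 (3.40), Usp18 (3.40), Ms4a6b (3.31) and Oasl2 (3.27). The largest falls were in Tlcd4 (-2.51), Zfp934 (-2.14), Cap1 (-1.98), Dnmt3b (-1.85), Prokr1 (-1.71), Mir1949 (-1.66), the haem synthesis gene Cpox (-1.64) and Prss12 (-1.63). Of 26 interferon genes 25 rose, 26 adjusted over the list alone (median 1.07; adjusted p = 7.67e-20; adjusted p = 0.0158 with an estimated correlation), against 14 of 26, 15 adjusted over the list alone, in the wild type (median 0.49; adjusted p = 3.44e-06; adjusted p = 0.122 with an estimated correlation). Of 27 haematopoietic genes 19 rose, and 19 rose and 1 fell adjusted over the list alone (median 0.79; adjusted p = 1.16e-09; adjusted p = 0.0166 with an estimated correlation). Of the 22 lists 7 passed in the knockout, and these 2 held with an estimated correlation. Of 34 primitive erythroid genes 17 fell and 1 rose, 19 and 1 adjusted over the list alone, including the haem synthesis gene Alad (-1.41) and the transcription factor Gata1 (-1.29), with a median of -0.58 (adjusted p = 6.33e-08; adjusted p = 0.545 with an estimated correlation). In the wild type 6 fell and 2 rose, also adjusted over the list alone (median -0.003; adjusted p = 0.146). The stage changes of the genotypes correlated across genes with r = 0.783, and 1683 genes rose in both, where independent lists would share 350, and 1028 fell in both, where 148 would be shared.

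The knockout effect at E10.5 was also set against the normal change between stages. Of the 2432 genes that rose in the wild type, 307 were lower in the E10.5 knockout, where independent lists would share 76.9, among them Alb, Ppbp, Msmo1 and Rhd. Of the 1612 that fell, 153 were higher in the knockout, where 66.5 would be shared, among them Fli1, Ccn2, Vegfa and Ccnd1. The knockout also had higher values for 128 of the genes that rose, where 100 would be shared, and lower values for 22 of those that fell, where 51.0 would be shared. Over the 626 genes that changed at least 2-fold in the wild type, the knockout reached a median of 79.6% of the wild type change (quartiles 56.6% and 104%), against 97.2% to 100.7% in simulations of an unchanged knockout. Those simulations started from the observed wild type means of genes chosen on the same arrays, and drew genes independently. They leave out part of the effect of that choice, so they are no test of the 79.6%. The knockout and stage comparisons both use the wild type E10.5 arrays, with opposite signs, which alone gives a negative correlation. Here r was -0.242 (jackknife SE 0.087), against -0.501 in simulations with no effect of knockout or stage. The stage change present in the data widens the spread that r is divided by, so these r values cannot be compared. The covariance was -0.0330, against -0.0117 simulated, a difference of -0.0213. With 3 wild type arrays the shared group could not be split into parts of at least 2 arrays, so part of the overlap may come from the shared arrays.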

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

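The tests of white blood cells, of the batch for the interferon list and for cholesterol at E10.5, of endoderm and of heart and embryo tissue were chosen only after the result was seen, and the criteria for white blood cells, heart and embryo tissue were made stricter after their values were seen. The criteria first written would have counted against these explanations, and the stricter ones leave them open. Bootstrap intervals resample the genes of a list and not the pools, so they do not measure the spread between pools.

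The knockout effect differed between E9.0 and E10.5, by limma's test of the difference, for 34 genes. Of 100 drawn splits of the arrays, the real one included, 11 gave at least 34 genes, and the highest other split gave 419, several times the real count. In all 10 of those other splits the E10.5 arrays kept their genotypes, and in 7 the genotypes were opposed between stages, so the structure they carry is the E10.5 knockout effect and they do not show what chance gives. The 88 splits that mixed the E10.5 arrays gave at most 1 gene, but they also remove that effect, so the splits do not decide whether chance can be excluded for this count. The 10 largest differences, at E10.5 minus E9.0, were Tnnt2 (2.95), Oasl2 (2.83), Shisa3 (2.59), Ifit1 (2.51), Ccl12 (2.33), Alb (-2.27), Lypd8 (-2.21), Prdm14 (-2.12), Ppbp (-1.97) and Cltrn (-1.50). Alb, Lypd8, Prdm14 and Ppbp were low at E9.0 in both genotypes, so a fall in the E9.0 knockout could hardly be seen.

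The test of the difference also passed for 16 of the 22 lists. Median differences were 0.53 for interferon response and -0.66 for cholesterol synthesis, which held with an estimated correlation. The others did not hold with it: histone genes (0.44), erythroid cells (-0.43), mesenchyme (0.34), endothelium (0.33), haematopoietic cells (0.25), hypoxia response (0.24), visceral endoderm (-0.21), the Notch pathway (0.20), vascular remodelling (0.15), oxidative phosphorylation (-0.14), p53 targets (0.12), imprinted genes (0.10), embryo proper (0.10) and nutrient uptake (-0.077). Within replicates 1 and 2 the medians were 0.42 for interferon and -0.79 for cholesterol, and the p53 list did not pass (adjusted p = 0.0998). Probe sets without a unique gene name, 932 with several symbols and 9160 with no entry, entered no gene test. In the fit on all probe sets 24 of them changed at E9.0 and 131 at E10.5, out of 183 and 1640 changed probe sets in all.

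Interferon response genes were higher in the E10.5 knockout, with a list median of 0.49. The batch seen in the control probes holds both genotypes, so a shift shared by its arrays cancels in the genotype difference. The median of 0.51 within replicates 1 and 2 also argues against this batch. Replicate 3 gave 0.52, but it is 1 array against 1 and gives no test. More white blood cells in the knockout pools stay open: the median of 16 white blood cell markers was 0.148, and the interferon median exceeded it by 0.345 with a 95% bootstrap interval from -0.088 to 0.902. The markers' own interval, -0.067 to 0.48, ended under the interferon median, which the criterion first written counted against this explanation. It is open only under the stricter criterion. Cx3cr1 rose, as did Csf1r and Tyrobp, named after their values were seen, while Fcgr3 fell by 1.82, so these markers did not move as a set. A response of the yolk sac cells to loss of Setd2 may also account for the pattern and was not tested.

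Cholesterol synthesis genes were higher in the knockout at E9.0 (adjusted p = 0.139 with an estimated correlation) and lower at E10.5 (adjusted p = 0.279 with an estimated correlation), so neither list call held with it. The batch is argued against at E9.0, where the median was 0.495 within replicates 1 and 2. At E10.5 the median of -0.35 within replicates 1 and 2 argues against it too. Replicate 3 gave 0.55 at E9.0 and -0.17 at E10.5, but it is 1 array against 1 and gives no test. The visceral endoderm list showed no rise at E9.0 that would go with a larger share of endoderm. Its median was -0.027 with a 95% bootstrap interval from -0.123 to 0.057, under a bound of 0.244 set from the cholesterol median. The interval leaves out the spread between pools, so a changed share is not excluded. At E10.5 the endoderm median was -0.13 with an interval from -0.25 to -0.04, which includes its bound of -0.14, so a smaller share of endoderm cannot be told apart from lower expression there. Since wild type cholesterol genes rose with stage by a median of 0.77 (adjusted p = 0.122 with an estimated correlation), slower development may contribute to the lower values at E10.5 and was not tested.

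Of 23 heart muscle genes, listed after Myl7 and Tnnt2 were seen to rise and given no set test, 7 rose in the E10.5 knockout and 0 at E9.0, where the median was -0.127 with a 95% bootstrap interval from -0.427 to -0.07. Without Myl7 and Tnnt2 the E10.5 median was 0.317; Myl4 (2.11), Nppb (0.90), Smpx (0.90), Tnni1 (0.65) and Tnnc1 (0.53) rose, while Actc1 (1.6; adjusted p = 0.0880), Nkx2-5 (-0.043) and Tbx5 (0.06) did not pass, all chosen after their values were seen. Heart tissue carried over in dissection may explain the rise, but 17 of the 21 are too dim to decide. The 4 brighter ones, Myl4, Actc1, Tnni1 and Tnnc1, had an E10.5 median of 1.123, and 3 of them rose. Myl4 is among them only through its E10.5 knockout arrays, so this choice may raise the median. Myl7, Myl4, Tnnt2 and Actc1 were highest in knockout replicate 1. Levels also varied between pools of 1 genotype. In E9.0 wild type replicates 1, 2 and 3 Myl7 was 5.32, 6.95 and 8.05, while Tnnc1 was 7.95, 8 and 8. Carried-over embryo tissue of all kinds also stays open: neural and somite genes had a median of 0.075, with 17 of 18 dim, while Sox11 and Crabp1 rose. No biological explanation was tested.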

How the results depend on the processing

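The batch block, replicates 1 and 2 alone, and the 6 arrays with a replicate block were chosen after seeing the data. At E9.0 the 215 changed genes became 876 with array weights, 61 on 6 arrays, 45 with a 2-fold minimum, 476 with the batch block, 69 in replicates 1 and 2, and 0 by limma on 6 arrays with a replicate block (3172 at an unadjusted p under 0.05). Leaving out 1 array gave 33 to 182. At E10.5 the 1325 became 873 over genes brighter than the median gene, 773 on 6 arrays, 284 with a 2-fold minimum, 2081 with the batch block, and 693 to 1630 without 1 array. The difference between stages, 34 genes, became 0 over the brighter genes (680 at an unadjusted p under 0.05), 148 with array weights, 61 with a replicate block, 91 with the batch block, and 12 to 90 without 1 array. Stage changes in the wild type were 6463 over all probe sets, 6291 with array weights and 626 with a 2-fold minimum. In the knockout they were 6488 and 633 for all probe sets and the 2-fold minimum. The 2-fold minimum removes calls by construction. For the other changes the cause was not tested.

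Of the lists, 3 passed at E9.0 and 16 at E10.5. These became 0 and 1 with an estimated correlation, and 1 and 9 with fry, which tests whether a list's genes move 1 way on balance and does not compare them with other genes; without 1 array they were 2 to 4 and 14 to 16. The correlation between stages was 0.571 over the brighter genes and 0.401 to 0.496 without 1 array. That with the stage change was -0.312 to -0.193. Setd2 ranged from -1.445 to -1.215 at E9.0 and from -0.92 to -0.77 at E10.5.

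Over 158 called results of named genes, leaving out 1 array kept the direction in all 1050 fits and the call in 798. A direction cannot turn in this way where the arrays of the groups do not overlap, so it was fixed in advance for such genes. Replicates 1 and 2 alone kept 117 calls, a further quantile normalisation 152, and the batch blocks all 158. Of 137 other probe sets 60 passed, 70 did not pass and 7 were opposite; among the 70, that of Prokr1 gave 0 in the knockout stage comparison.

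Opposite signs from other probe sets were -0.09 for Cldn1, -0.057 for Snap91, -0.123 for Afp and -0.007 for Hbb-bh1 at E9.0. At E10.5 they were 0.04 for Rbpj, 0.23 and 0.163 for Dnmt3a, 0.08 for Msmo1, -0.15 for Ndn, and -0.057 and -0.02 for Afp. Near-zero uncalled changes also turned. Kdr at E9.0 gave -0.21 to 0.173 without 1 array and -0.04 in replicates 1 and 2. At E10.5 Tek gave -0.013 to 0.302 and Afp -0.027 to 0.033, with -0.005 in replicates 1 and 2. The cause was not tested.

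A replicate block gave 286 genes at E9.0 and 1605 at E10.5, and kept 154 of the 158 calls of named genes. The others were Cldn1 (adjusted p = 0.0505) and Itgb3 (0.0504) at E9.0, Pecam1 at E10.5 (0.0632) and Tnnt2 for the difference between stages (0.0542). Whether the replicate numbers pair the samples cannot be told from these arrays. Same-number correlations were 0.034, 0.225 and 0.241 at E9.0 and 0.255, 0.067 and 0.401 at E10.5. Replicate 3 at both stages, replicate 2 at E9.0 and replicate 1 at E10.5 correlated best with their own number. Replicate 1 at E9.0 and replicate 2 at E10.5 did not. Leaving out genes within 10 Mb of Setd2 was not run for the stage comparisons within a genotype. In fits that leave 1 array out, the smaller group keeps 2 arrays. Precision limits small changes: in the simulation 18 of 66 genes moved by 0.5 were recovered at each stage. The simulation did not test the compression of dim signals or the correlation between genes.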

Other observations

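All tests of this part, the flank of Setd2 and the splits of the arrays, were set before their results were seen.

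A knockout may keep the chromosome segment around the targeted gene from the cells in which it was made, so strain variants near Setd2 could mimic expression changes. The origin of this segment is not known here. Of the 118 positioned genes changed at both stages in the same direction, 3 (2.54%) lie within 10 Mb of Setd2, against 241 of 18031 genes (1.34%), and a one-sided Fisher exact test gave p = 0.21. The 3 genes are Nme6, Hemk1 and Rab6b, the first and second named after their values were seen. On the whole chromosome of Setd2 lie 12 of the 118, where 6.56 would lie by its share of all genes, so a longer carried segment stays open for these. The other shared changes lie on other chromosomes, so most of them are not variants within the segment itself. Effects of the segment on genes elsewhere, and strain variants elsewhere, were not tested.

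For each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. In each comparison only 1 of the 10, the real one, gave as many genes. The real counts and the highest of the other splits were 215 and 1 at E9.0, 1325 and 0 at E10.5, 4044 and 0 for the stage change in the wild type, and 4290 and 0 for that in the knockout. Every other split mixes the real groups, which moves their difference into the spread. These low counts therefore do not show what chance gives.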
